A study of Homo sapiens with 8 samples.

How the data were processed

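Poly(A) RNA was measured in 8 libraries of HCT116, a human colorectal carcinoma line with a functional p53 gene, that carried CRISPR interference (CRISPRi), in which a catalytically inactive Cas9 joined to a repressor domain is led to a promoter by a guide RNA. There were 4 groups of 2 libraries: the parental CRISPRi line with a control guide (parental sgControl), the parental line with a guide against NORAD (parental sgNORAD), and the lines called circPRE2 and circPRE8 in the labels, each with the NORAD guide. The labels do not describe what circPRE2 and circPRE8 are, and the names are used here only as names. Per the labels' protocols, cells were grown in McCoy's medium with serum, RNA was column-purified with DNase digestion, poly(A) RNA was selected on oligo-dT beads, and libraries were sequenced by a service provider as paired Illumina reads. Groups and replicate numbers were taken from the sample titles and the genotype and guide labels.

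The authors deposited 1 table of RPKM values (reads scaled to gene length and library size) for 19411 genes, of which 19363 are protein-coding in GENCODE release 29. The submitters' processing notes name STAR (no version), featureCounts 1.6.0, edgeR 3.24.0 and the genome build hg38. The annotation release, the use of strand in counting and any filter are not given in the sources used here. A design text attached to the series describes triplicates and a small RNA kit, which differ from these duplicate poly(A) libraries, and it was not used. Because counting is not stated to use strand, reads of overlapping genes and antisense partners, and of near-identical copies such as ribosomal protein and histone genes and their pseudogenes, may be shared, and values of such genes are uncertain to that extent.

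All columns of the table were used (0 left unused). Of the gene identifiers, 19379 matched GENCODE release 29, from which coordinates (1-based, hg38) were taken. Symbols that a spreadsheet had turned into date numbers were restored from the identifier for 27 genes, and 34 symbols stood at more than 1 identifier and were kept apart by identifier. There were 2061 genes at 0 in every library and 17350 above 0 in at least 1. RPKM steps at low values gave the library size used in the deposited scaling and then whole reads: 10582 genes came out whole, within 0.1 read in all 8 libraries, with the merged exon length of GENCODE release 29, and for the others the shortest length that made all values whole was taken. Reads were obtained in this way for all 17350 genes (100%). With the annotated lengths alone, between 80.2% and 81.4% of the low values in a library were whole. The lengths found without annotation are fitted values, so reads serve here for depth, for the minimum level of named genes, for the read numbers given for IL32 and APOBEC3G, for the chi-square between replicates and for an added alternative test.

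The scaling sizes (M, megareads) were 42.57 and 44.87 M for parental sgControl, 28.39 and 45.7 M for parental sgNORAD, 46.25 and 50.28 M for circPRE2 sgNORAD, and 44.65 and 49.27 M for circPRE8 sgNORAD (replicates 1 and 2). At these depths, 1 read for a gene of 1 kb stood for 0.0199 to 0.0352 RPKM. Counting error alone is covered by these figures, since PCR copies are not independent molecules.

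Values were tested as log2(RPKM + 0.1) with the deposited scaling, for the 11585 genes with at least 0.5 RPKM in at least 2 libraries. A linear model with 1 coefficient per group was fitted over all 8 libraries with limma 3.58.1 in R 4.3.3, with an intensity trend in the moderated variance (4 residual degrees of freedom, 11.6 after moderation), and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. A fold change is the antilog of the difference of mean log2(RPKM + 0.1), so it understates the change of low genes. Standard deviations are of RPKM over 2 libraries. A test for counts had been planned before the data were examined; it was replaced by limma because the table holds RPKM and not counts. The groups, comparisons, gene lists, the rule for named genes and most alternatives were also fixed before the data were examined.

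Gene lists were tested with camera (limma) at a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation and with fry, which tests only whether the genes of a list move one way on balance and does not compare them with other genes. There were 23 fixed lists: PUMILIO targets named in the literature; NORAD, PUMILIO and CCR4-NOT factors; NORAD chromosome 20 neighbours; mitosis and chromosome segregation; cohesin and condensin; DNA replication; DNA repair and damage checkpoint; p53 targets; interferon and double-stranded RNA response; integrated stress and unfolded protein response; heat shock; cholesterol biosynthesis; hypoxia and glycolysis; Wnt target and intestinal stem cell genes; intestinal epithelial differentiation; epithelial-mesenchymal and TGF-beta response; ribosomal proteins; nuclear-encoded oxidative phosphorylation; mitochondrially encoded genes and replication histones without a poly(A) tail (both as signs of RNA quality); and markers of fibroblasts, blood, and embryonic kidney and neural lines (other cells). For PUMILIO motifs, the longest annotated 3' UTR of each of 11542 tested protein-coding genes was searched for UGUA, then any base except G, then AUA. The reversed motif served as a control, as did 1000 random gene lists matched on 3' UTR length, or on length and GC content.

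Named genes followed a rule: PUM2 in every comparison, then the 8 largest rises and the 8 largest falls among genes with adjusted p under 0.05, a mean of at least 5 CPM (reads scaled to library size) in the higher group and no overlap between the libraries of the groups, then up to 3 members of each fixed list with the smallest adjusted p under 0.05. NORAD was on the same rule and was not analysed here. From these, genes are named in the text as examples, and some genes chosen by the rule are not reported here.

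Simulated log2 values were drawn around the mean of each real gene, with the spread that the fit gave that gene. These values were normal, independent between genes and equal in spread across groups. The assumptions of the fit thus held by design, and its behaviour on the real libraries was not tested in this way. The fit was run on the simulated values with 200 genes changed per run over 20 runs. For parental sgNORAD against parental sgControl, with 11585 genes, it recovered 75.9% of genes changed 1.25-fold, 93.7% of those changed 1.5-fold, 99.8% of those changed 2-fold and 100% of those changed 4-fold, with 12.9 false calls per run and 0.45 calls per run when no gene was changed.

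Alternatives were RLE size factors, upper quartile factors and library totals applied to the RPKM values, no filter, a stricter filter of 1 RPKM in both libraries of a group, a fit on only the 4 libraries compared, the replicate number as a block, limma's treat against a log2 change of 0.5, and leaving out each library in turn. Pseudocounts of 0.01 and 1 and limma voom on the recovered reads were added after the data were seen, as was the overlap of circPRE2 and circPRE8 changes with a separate parental sgNORAD library as the control of each. The planned count-based tests were not run because the unit does not permit them as a main result. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.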

Results

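Messenger RNA was measured by poly(A) RNA sequencing in HCT116 colorectal carcinoma cells that carried CRISPR interference, a way of silencing a gene at its promoter. The title of the series links the long noncoding RNA NORAD, which binds PUMILIO proteins, with phase separation of PUMILIO and genome maintenance. There were 4 groups of 2 libraries each: the parental line with a control guide (parental sgControl), the parental line with a NORAD guide (parental sgNORAD), and the lines circPRE2 and circPRE8, each with the NORAD guide. The labels do not describe circPRE2 or circPRE8. Reads recovered for genes (M, megareads) came to 39.85 and 42.25 M in parental sgControl, 27.02 and 42.37 M in parental sgNORAD, 43.04 and 46.77 M in circPRE2 sgNORAD, and 41.66 and 45.45 M in circPRE8 sgNORAD. Between 15363 and 15934 of 19411 genes were above 0 in a library, and 11585 were tested.

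Values are mean RPKM ± SD (SD, n = 2 libraries per group), fold changes are antilogs of differences in mean log2(RPKM + 0.1), and p-values are from limma with Benjamini-Hochberg adjustment unless another test is named. Coordinates are hg38 with genes of GENCODE release 29. The p-values measure only the spread between 2 libraries per group, which may be technical, and do not measure spread between independently made lines. Root mean square log2 differences between replicates were 0.125 in parental sgControl, 0.149 in parental sgNORAD, 0.11 in circPRE2 sgNORAD and 0.125 in circPRE8 sgNORAD.

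NORAD (ENSG00000260032, chromosome 20, 36045622 to 36050960) was the gene targeted by the guide. Its level was not analysed here, so the knockdown was not checked in any library. PUMILIO proteins, which NORAD binds, repress messenger RNAs that carry their motif. PUM2 (ENSG00000055917.15, chromosome 2, 20248691 to 20352234) stood at 28.2 ± 0.827, 28 ± 2.01, 27.7 ± 1.15 and 28.9 ± 0.793 RPKM (SD, n = 2) in parental sgControl, parental sgNORAD, circPRE2 sgNORAD and circPRE8 sgNORAD. It passed in no comparison (limma with Benjamini-Hochberg adjustment).

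The comparison of parental sgNORAD with parental sgControl asked what the NORAD guide changed in the parental line. The largest rise was that of IL32, an inflammatory cytokine gene (ENSG00000008517.16, chromosome 16, 3065297 to 3082192), from 0.0249 ± 0.00411 to 7.82 ± 0.168 RPKM (SD, n = 2; 63.4-fold, limma with Benjamini-Hochberg adjusted p = 2.5e-11). MMP14, a membrane-bound matrix metalloproteinase (ENSG00000157227.13, chromosome 14, 22836557 to 22849027), rose 7.6-fold to 4.3 ± 0.202 RPKM (adjusted p = 8.08e-08). The RNA-binding protein gene IGF2BP3 rose 5.01-fold to 10.9 ± 0.372 RPKM (adjusted p = 6.32e-10), and RGS2, a regulator of G protein signalling, rose 5.48-fold to 8.62 ± 0.472 RPKM. The arrestin relative ARRDC4 rose 9.54-fold, the laminin gene LAMA4 4.8-fold, the desmosomal cadherin gene DSC3 4.42-fold and the stem cell marker PROM1 3.87-fold. The Notch ligand relative DNER fell to 0.367 of the control level (0.774 ± 0.134 against 2.27 ± 0.195 RPKM, adjusted p = 2.02e-06), and TWIST1, a transcription factor of mesenchymal cells, fell to 0.371. The circadian repressor BHLHE41 fell to 0.39, the splicing regulator MBNL3 to 0.399 and NETO2, an auxiliary subunit of glutamate receptors, to 0.418.

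IL32, parental sgNORAD against parental sgControl, rested on 3 and 4 reads in the control libraries and on 723 and 1129 reads with the NORAD guide. Its log2 change was 5.99 with the pseudocount of 0.1, 7.82 with 0.01 and 3.11 with 1, so the size of this rise depends on the constant added, while the RPKM levels do not.

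In the same comparison, genes of mitosis fell: of 36 tested, 0 rose, 34 fell and 2 did not pass (0 and 34 adjusted over the list alone). Examples were the cytokinesis gene ANLN at 0.728 of control (42.4 ± 2.53 against 58.3 ± 0.84 RPKM, limma with Benjamini-Hochberg adjusted p = 2.46e-05), the cyclin gene CCNB2 at 0.762 and the kinetochore gene SPC25 at 0.773. Of 44 DNA replication genes, 0 rose, 24 fell and 20 did not pass (0 and 27 adjusted over the list alone), among them the ribonucleotide reductase subunit RRM2 at 0.762, the origin factor ORC6 at 0.8 and the loading factor CDC6 at 0.782. Of 21 cohesin and condensin genes, 3 rose and 11 fell (4 and 12 adjusted over the list alone), with the cohesin regulator CDCA5 at 0.815 and the condensin subunit NCAPG at 0.82. Of 26 p53 target genes, 21 rose and 0 fell (23 and 0 adjusted over the list alone). CDKN1A, which encodes the cell cycle inhibitor p21 (ENSG00000124762.13, chromosome 6, 36676460 to 36687339), rose 1.69-fold from 88.1 ± 5.21 to 149 ± 1.63 RPKM (SD, n = 2; adjusted p = 4.46e-07), the stress protein gene TP53INP1 rose 2.15-fold to 10.2 ± 0.0732 RPKM and the growth factor gene GDF15 rose 1.59-fold to 142 ± 0.606 RPKM. Of 25 genes of the interferon and double-stranded RNA response, 15 rose and 0 fell (16 and 0 adjusted over the list alone), with OASL up 2.27-fold, the ubiquitin ligase relative HERC6 up 1.52-fold and the ubiquitin-like ISG15 up 1.39-fold to 65.5 ± 2.54 RPKM.

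Of 25 integrated stress and unfolded protein response genes, 1 rose and 16 fell (2 and 16 adjusted over the list alone), with the serine synthesis enzymes PHGDH at 0.641 and PSAT1 at 0.744 and the endoplasmic reticulum factor MANF at 0.782. Of 22 genes of cholesterol biosynthesis, 2 rose and 15 fell (2 and 16 adjusted over the list alone), with the sterol carrier STARD4 at 0.617, the sterol oxidase MSMO1 at 0.683 and the synthase FDPS at 0.737. Of 36 ribosomal protein genes, 26 rose and 0 fell (29 and 0 adjusted over the list alone; 18 and 0 with RLE size factors), with RPS18 up 1.24-fold, RPL3 up 1.19-fold and RPL10 up 1.18-fold. Of 32 nuclear-encoded genes of oxidative phosphorylation, 11 rose and 0 fell (10 and 0 adjusted over the list alone; 6 and 1 with RLE size factors), with the complex I subunit NDUFV1 up 1.28-fold and the complex III subunit UQCRC2 up 1.15-fold. Of 20 hypoxia and glycolysis genes, 3 rose and 8 fell (3 and 9 adjusted over the list alone): the glucose transporters SLC2A1 and SLC2A3 fell to 0.741 and 0.642, and the hexokinase gene HK2 rose 1.32-fold. Among single genes of other lists, the growth regulator MYC (ENSG00000136997.18, chromosome 8, 127735434 to 127741434) rose 1.57-fold from 58.9 ± 0.882 to 92.6 ± 0.678 RPKM (limma, Benjamini-Hochberg adjusted p = 5.93e-07). The intestinal transcription factor SOX9 fell to 0.758 and CCN2, a matrix signalling gene, to 0.584. The DNA end-joining kinase gene PRKDC rose 1.69-fold, with 50 ± 10.4 against 29.2 ± 2.95 RPKM.

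The set test camera, at a preset correlation between genes of 0.01 and with Benjamini-Hochberg adjustment, gave for these lists adjusted p = 1.78e-16 for mitosis, 6.01e-09 for DNA replication, 0.00653 for cohesin and condensin, 2.73e-12 for p53 targets, 4.22e-05 for interferon, 4.32e-06 for integrated stress, 8.39e-08 for cholesterol, 5.89e-08 for ribosomal proteins, 0.0133 for oxidative phosphorylation and 0.016 for hypoxia. None of these calls, nor any fixed-list call in the other comparisons, held when the correlation was estimated from these 8 libraries. Adjusted p = 0.496 with an estimated correlation for mitosis and cholesterol, 0.303 for p53 targets, 0.623 for oxidative phosphorylation and 0.558 for the others. The member counts above do not depend on the set test. Without parental sgControl replicate 1 the oxidative phosphorylation call was lost (adjusted p = 0.144) and heat shock was called (adjusted p = 0.0136, against 0.0644 with all libraries). Ribosomal rises went as low as 15, oxidative phosphorylation rises 6, cohesin and condensin falls 7 and hypoxia rises 1 without that library. When parental sgControl replicate 2 was left out instead, cohesin and condensin rises went to 1 and heat shock falls from 6 to 2.

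The other lists were not called in this comparison (camera with Benjamini-Hochberg adjustment). Risen and fallen members were 1 and 6 of 14 heat shock genes (1 and 7 adjusted over the list alone), 8 and 16 of 43 DNA repair genes (9 and 16 adjusted over the list alone) and 1 and 2 of 9 PUMILIO targets (1 and 2 adjusted over the list alone). They were 5 and 0 of 21 NORAD, PUMILIO and CCR4-NOT factors (4 and 0 adjusted over the list alone), and 3 and 7 of 14 Wnt and stem cell genes (3 and 8 adjusted over the list alone). For 8 intestinal differentiation genes they were 1 and 2 (2 and 2 adjusted over the list alone), and for 14 epithelial-mesenchymal genes 4 and 6 (5 and 6 adjusted over the list alone). The median and mean log2 change differed in sign for intestinal differentiation (-0.01 and 0.031) and epithelial-mesenchymal genes (-0.119 and 0.028). Of 4 mitochondrially encoded genes 0 rose and 0 fell, of 11 replication histone genes 3 rose and 1 fell (3 and 1 adjusted over the list alone), of 3 fibroblast markers 1 rose and 0 fell (1 and 0 adjusted over the list alone), and of 3 embryonic kidney and neural markers 0 rose and 0 fell. The 1 blood marker tested, CORO1A, rose 1.26-fold (adjusted p = 0.0308), but not with any parental sgControl, parental sgNORAD or circPRE2 sgNORAD library left out. Leaving out parental sgNORAD replicate 2 gave the mitochondrially encoded genes an adjusted p of 0.000127 (0.454 with all libraries), and leaving out parental sgNORAD replicate 1 changed the sign of their median. Mitochondrially encoded genes took 4.01% of summed RPKM in parental sgNORAD replicate 1 and 8.34% in replicate 2. Without parental sgControl replicate 2, rises went to as few as 2 among CCR4-NOT factors, 5 in DNA repair and 0 among fibroblast markers, and falls to 0 among PUMILIO targets, and without replicate 1 of that group falls in DNA repair went to 10. Repair genes that moved included the recombination motor RAD54L at 0.74 and the checkpoint mediator CLSPN at 0.779.

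Of 14 tested neighbours of NORAD on chromosome 20, 4 rose and 3 fell (5 and 3 adjusted over the list alone; camera with Benjamini-Hochberg adjusted p = 0.306; fry adjusted p = 0.000735). CPNE1, a calcium-dependent membrane-binding protein gene 380.7 kb away, rose 1.65-fold from 16.9 ± 0.311 to 27.9 ± 0.541 RPKM (limma, Benjamini-Hochberg adjusted p = 2.91e-07), and RBM12, an RNA-binding protein gene that overlaps it on the same strand, fell to 0.849. Reads of CPNE1 and RBM12 may be split between them by the counting, so both are uncertain. SCAND1 rose 1.17-fold (86.2 kb away, adjusted p = 0.00668) and PHF20, a chromatin reader gene, fell to 0.873 (95.2 kb away, adjusted p = 0.0295). Of protein-coding genes with at least 1 PUMILIO motif in the 3' UTR (3159 of 11542), the median log2 change relative to other genes was -0.001, and of those with at least 2 (1042) it was 0.01, and neither was called (camera with Benjamini-Hochberg adjusted p = 0.938 for each).

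Across all 11585 genes in this comparison, 2425 rose and 1901 fell (4326, 37.3%), of which 48 rose and 36 fell more than 2-fold. Against a log2 change of 0.5, 54 rose and 45 fell (limma treat). Of the genes called, 56.1% rose, but 47.8% with RLE size factors and 46.4% with upper quartile factors, so which direction held the majority depended on the scaling. The IL32, CDKN1A and ANLN results rest on 2 libraries per group, and this comparison alone cannot separate the guide from other differences between the cultures.

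**Figure D1:**
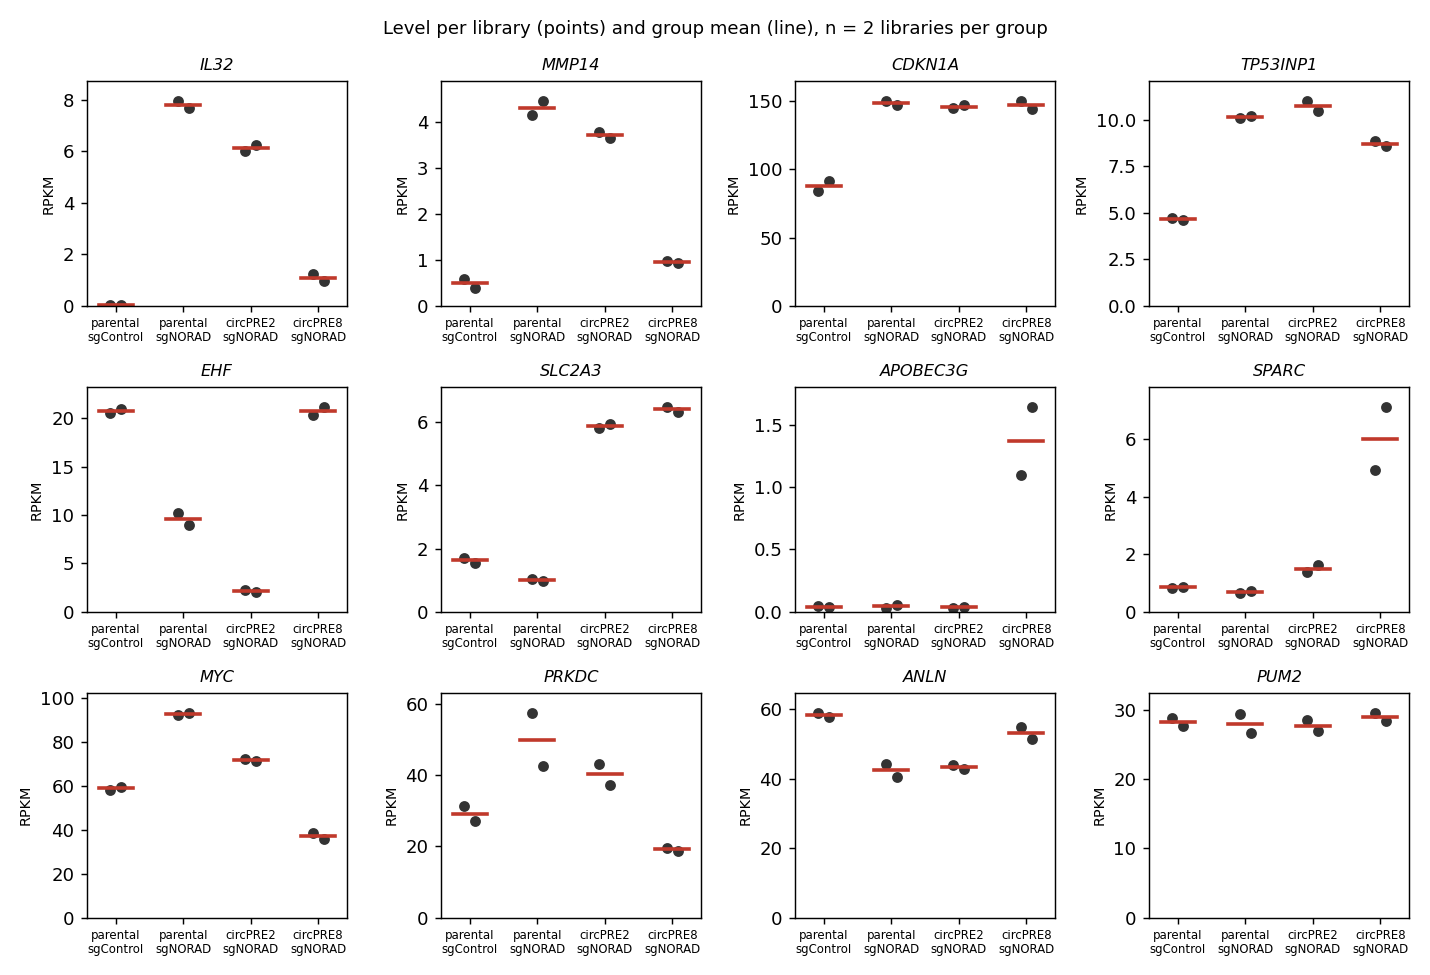
Levels of 12 genes in RPKM (vertical axes) per library (points) and group mean (lines) in the 4 groups. IL32 rose from 0.0249 RPKM in parental sgControl to 7.82 in parental sgNORAD and stood at 1.09 in circPRE8 sgNORAD, and EHF stood at 2.16 in circPRE2 sgNORAD and 20.7 in circPRE8 sgNORAD.

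**Figure D2:**
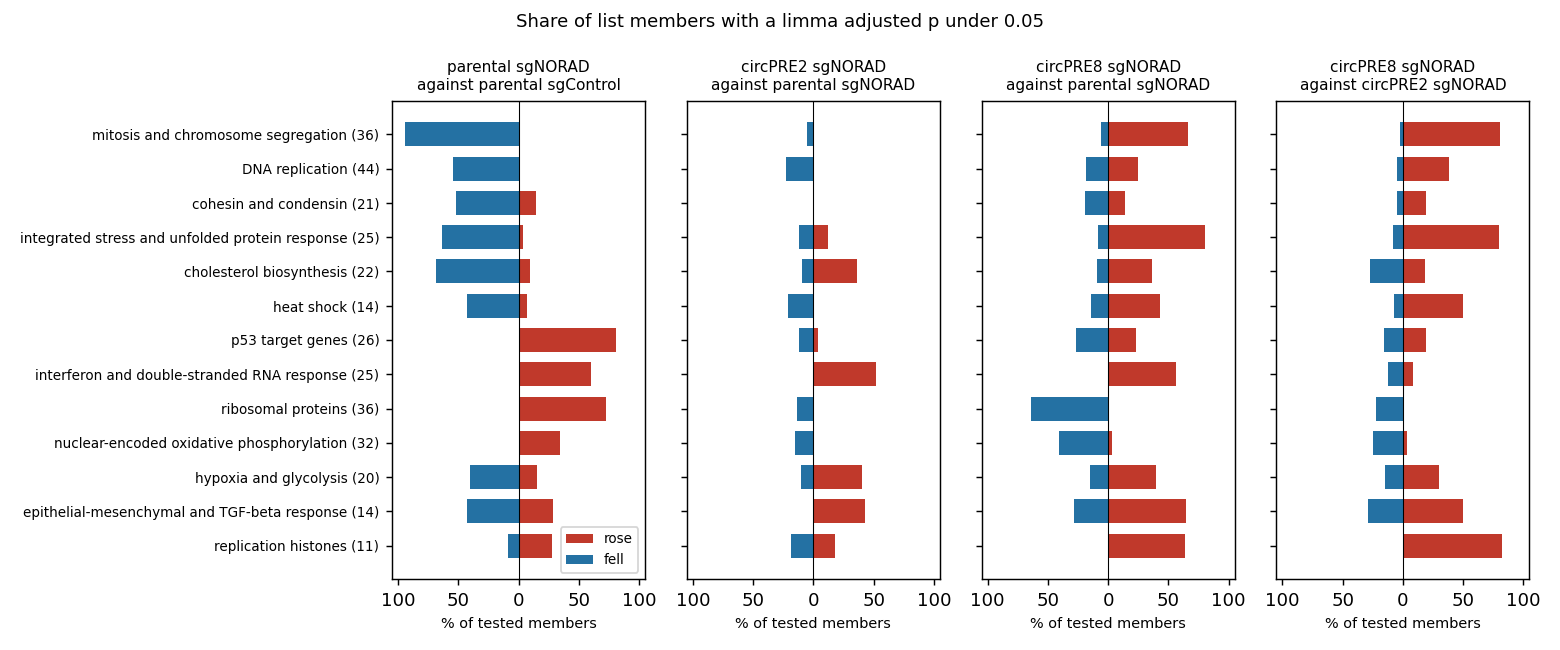
Percentage of tested members of 13 gene lists that rose (red, to the right) or fell (blue, to the left) with adjusted p under 0.05, in 4 comparisons with 2 libraries per group. Mitosis genes fell (34 of 36) with the NORAD guide in the parental line and rose (29 of 36) in circPRE8 against circPRE2.

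Next, circPRE2 sgNORAD was set against parental sgNORAD, to ask what differed with circPRE2 when each line had the NORAD guide. SLC2A3, a neuronal-type glucose transporter gene (ENSG00000059804.16, chromosome 12, 7919230 to 7936275), rose 5.38-fold from 1.01 ± 0.0478 to 5.87 ± 0.0882 RPKM (SD, n = 2; limma, Benjamini-Hochberg adjusted p = 3.55e-09). EHF, an epithelial ETS-family transcription factor gene (ENSG00000135373.12, chromosome 11, 34621093 to 34661057), fell to 0.233 of its level, from 9.62 ± 0.863 to 2.16 ± 0.134 RPKM (adjusted p = 3.55e-09). The secreted Wnt antagonist DKK1 rose 2.24-fold to 157 ± 4.19 RPKM (adjusted p = 7.51e-09), and the interferon-induced IFI6 rose 2.39-fold to 43 ± 4.38 RPKM (adjusted p = 0.000318). The keratin gene KRT23 rose 4.24-fold, the guidance cue SEMA3A 3.96-fold, the coagulation factor gene F10 3.5-fold, SAMD5 3.41-fold and the integrin subunit ITGB8 2.32-fold. The keratin gene KRT7 fell to 0.447, the membrane protein gene EMP1 to 0.527, NAV3 to 0.549, the glutamate transporter SLC1A3 to 0.554 and the bone transcription factor RUNX2 to 0.563. PUM2 did not pass (adjusted p = 0.872).

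Of 25 interferon genes in this comparison, 13 rose and 0 fell (16 and 0 adjusted over the list alone; camera with Benjamini-Hochberg adjusted p = 4.38e-07), with SAMD9 up 1.53-fold and ISG15 up 1.3-fold. Of 14 epithelial-mesenchymal genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone; adjusted p = 0.000888), with CCN2 up 1.62-fold and the signalling inhibitor SMAD7 up 1.88-fold. Of 44 DNA replication genes, 0 rose and 10 fell (0 and 12 adjusted over the list alone; adjusted p = 7.05e-07). Ribosomal protein genes fell in 5 of 36 with 0 rises (0 and 3 adjusted over the list alone; adjusted p = 2.47e-06), with RPL14 at 0.871, and heat shock genes in 3 of 14 with 0 rises (0 and 5 adjusted over the list alone; adjusted p = 0.00312), with the chaperone DNAJA1 at 0.807. DNA repair genes gave 1 rise and 4 falls of 43 (0 and 0 adjusted over the list alone; adjusted p = 0.00211). Of 22 cholesterol genes, 8 rose and 2 fell (9 and 2 adjusted over the list alone; adjusted p = 0.00824), with STARD4 up 1.44-fold, TM7SF2 up 1.31-fold and the regulator SREBF2 at 0.832. Of 20 hypoxia and glycolysis genes, 8 rose and 2 fell (8 and 3 adjusted over the list alone; adjusted p = 0.0085), with SLC2A1 up 1.65-fold and the aldolase ALDOC up 1.48-fold. Adjusted p = 0.352 with an estimated correlation for epithelial-mesenchymal genes and 0.526 for the other lists of this paragraph. MYC fell to 0.775 and the adhesion gene EPCAM to 0.826, the Wnt feedback genes NOTUM and AXIN2 rose 1.56-fold and 1.5-fold, and SPARC, a matrix protein gene and fibroblast marker, rose 2.03-fold.

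Markers of other cells were not called in circPRE2 against parental sgNORAD (camera with Benjamini-Hochberg adjustment). Rises and falls were 1 and 0 of 3 for fibroblasts (1 and 0 adjusted over the list alone; 0.155), with 2 rises without circPRE8 sgNORAD replicate 1, and 1 and 0 of 3 for embryonic kidney and neural lines (1 and 0 adjusted over the list alone; 0.185), where PAX2 rose 1.52-fold. The blood marker CORO1A rose 1.28-fold (limma, Benjamini-Hochberg adjusted p = 0.0427) and was lost with any library left out.
Smaller calls in circPRE2 against parental sgNORAD hung on single libraries (camera with Benjamini-Hochberg adjustment). Oxidative phosphorylation (0 rises and 5 falls, 0 and 5 adjusted over the list alone; adjusted p = 0.0119) was lost without parental sgNORAD replicate 2 (0.0554) and without circPRE2 sgNORAD replicate 1 (0.11). Cohesin and condensin (0 and 0, with or without the other genes; 0.0145) was lost without parental sgNORAD replicate 1 (0.21). Mitosis (0 and 2, 0 and 2 adjusted over the list alone; 0.0396) went to 0.261 without parental sgNORAD replicate 1 and 0.46 without circPRE2 sgNORAD replicate 1. The CCR4-NOT factors (0 and 1, 0 and 1 adjusted over the list alone; 0.0215) went to 0.12 without parental sgNORAD replicate 1 and 0.0634 without circPRE2 sgNORAD replicate 2. Wnt and stem cell genes (5 and 1; 7 and 2 adjusted over the list alone; 0.0396) went to 0.128 without parental sgNORAD replicate 2 and 0.066 without circPRE2 sgNORAD replicate 2. Adjusted p = 0.67 with an estimated correlation for mitosis and 0.526 for the rest of these. Leaving out parental sgNORAD replicate 2 added a call for mitochondrially encoded genes (7.59e-06). When circPRE2 sgNORAD replicate 1 was left out, interferon rises went to as few as 8, cholesterol rises to 3, and falls to 2 in DNA replication, 1 in ribosomal proteins, 1 in heat shock and 0 in DNA repair, and 0 in oxidative phosphorylation. Without parental sgNORAD replicate 2, Wnt rises went to 3 and hypoxia falls to 1, while falls went up to 3 in cohesin and condensin, 4 among CCR4-NOT factors and 5 in heat shock. Mitosis falls went to 0 without parental sgNORAD replicate 1.

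In all, 1257 genes rose and 916 fell in circPRE2 sgNORAD against parental sgNORAD (2173 of 11585, 18.8%), with 34 and 5 beyond 2-fold and 19 and 4 against a log2 change of 0.5 (limma treat). Of the genes called, 57.8% rose, and 45.6% rose with RLE size factors. The total was 713 without circPRE2 sgNORAD replicate 1 (475 up, 238 down), 1210 without circPRE2 sgNORAD replicate 2 (724 up, 486 down) and 1439 without parental sgNORAD replicate 1 (1037 up, 402 down). SLC2A3 and EHF changed with every library left out.

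The comparison of circPRE8 sgNORAD with parental sgNORAD asked the same of circPRE8. The serine protease gene PRSS33 (ENSG00000103355.13, chromosome 16, 2783953 to 2787948) rose 15.4-fold from 0.2 ± 0.0241 to 4.52 ± 0.562 RPKM (SD, n = 2; limma, Benjamini-Hochberg adjusted p = 3.8e-08). SPARC (ENSG00000113140.11, chromosome 5, 151661096 to 151687165) rose 7.66-fold to 6.01 ± 1.54 RPKM, and the antiviral deaminase gene APOBEC3G (ENSG00000239713.9, chromosome 22, 39077005 to 39087743) rose 10-fold to 1.37 ± 0.381 RPKM (adjusted p = 9.55e-07). The growth factor binding protein gene IGFBP3 rose 7.41-fold, SLC2A3 5.86-fold, F10 5.02-fold, DNER 4.87-fold and SEMA3A 4.38-fold. IL32 fell to 0.149, from 7.82 ± 0.168 to 1.09 ± 0.198 RPKM (adjusted p = 8.71e-09), and MAL2, an apical transport gene of epithelia, fell to 0.15, from 69.8 ± 0.776 to 10.6 ± 2.94 RPKM. WDR72 fell to 0.18, ZNF711 to 0.201, the glycosyltransferase gene GALNT14 to 0.205, DSC3 to 0.206, ARRDC4 to 0.215 and MMP14 to 0.239. MYC fell to 0.403, from 92.6 ± 0.678 to 37.2 ± 1.86 RPKM (adjusted p = 1.21e-09). PUM2 did not pass (adjusted p = 0.459).

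Of 36 mitosis genes in circPRE8 sgNORAD against parental sgNORAD, 24 rose and 2 fell (24 and 2 adjusted over the list alone; camera with Benjamini-Hochberg adjusted p = 4.74e-06), with the kinesin KIF18A up 1.48-fold to 17.4 ± 0.759 RPKM, the kinase PLK1 up 1.31-fold and CCNB2 up 1.31-fold. Of 25 integrated stress genes, 20 rose and 2 fell (20 and 2 adjusted over the list alone; adjusted p = 1.26e-05), with the transcription factor ATF5 up 1.73-fold, PHGDH up 1.66-fold and the sestrin SESN2 up 1.43-fold. Ribosomal protein genes fell in 23 of 36 with 0 rises (0 and 25 adjusted over the list alone; adjusted p = 0.000103), among them RPL3 at 0.824, RPL37 at 0.845 and RPS6 at 0.852. Interferon genes rose in 14 of 25 with 0 falls (14 and 0 adjusted over the list alone; adjusted p = 0.00143), among them IFIT1 at 2.2-fold, IRF7 at 1.85-fold and SAMD9 at 1.65-fold. Replication histone genes rose in 7 of 11 with 0 falls (7 and 0 adjusted over the list alone; adjusted p = 0.00158), with HIST1H1C up 2.32-fold and HIST1H2BK up 1.87-fold; such messages mostly end without a poly(A) tail, so their level also depends on the selection of RNA. Epithelial-mesenchymal genes gave 9 rises and 4 falls of 14 (9 and 4 adjusted over the list alone; adjusted p = 0.0213), with the intermediate filament gene VIM up 3.78-fold, CCN2 up 2.12-fold and MMP14 down. Adjusted p = 0.798 with an estimated correlation for mitosis, integrated stress, ribosomal and interferon genes and 0.55 for histones and epithelial-mesenchymal genes. Without circPRE8 sgNORAD replicate 1 the falls among epithelial-mesenchymal genes went to 2, without parental sgNORAD replicate 1 those in mitosis and integrated stress to 1 each, and without parental sgNORAD replicate 2 those in interferon up to 3.

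Lists not called in that comparison still held genes that passed. The counts of rises and falls were 1 and 13 of 32 for oxidative phosphorylation (1 and 13 adjusted over the list alone; camera with Benjamini-Hochberg adjusted p = 0.0816), 6 and 18 of 43 for DNA repair (7 and 19 adjusted over the list alone; 0.248), 11 and 8 of 44 for DNA replication (9 and 8 adjusted over the list alone; 0.671), and 6 and 7 of 26 for p53 targets (6 and 7 adjusted over the list alone; 0.996). They were 8 and 2 of 22 for cholesterol (8 and 2 adjusted over the list alone; 0.0816, and 0.0237 without circPRE8 sgNORAD replicate 2) and 8 and 3 of 20 for hypoxia (9 and 3 adjusted over the list alone; 0.0777). The hypoxia list was called without parental sgNORAD replicate 1 (0.0355) and without circPRE8 sgNORAD replicate 1 (0.0396). Fibroblast markers (2 and 0 of 3; 2 and 0 adjusted over the list alone; 0.148) were called without circPRE8 sgNORAD replicate 1 (0.0143), and mitochondrially encoded genes (0 and 0 of 4; 0.318) without parental sgNORAD replicate 2 (0.000856), which also took fibroblast rises to 1. Embryonic kidney and neural markers gave 1 and 1 of 3 (1 and 1 adjusted over the list alone; 0.671). As few as 4 DNA replication rises and 3 repair rises were called without circPRE8 sgNORAD replicate 1, and as few as 11 repair falls and 2 p53 target falls without circPRE8 sgNORAD replicate 2. The end-joining gene XRCC4 rose 1.75-fold, PRKDC fell to 0.389 (19.2 ± 0.581 RPKM, limma with Benjamini-Hochberg adjusted p = 2.35e-06) and the recombination gene XRCC2 fell to 0.695. SLC2A1 rose 2.8-fold to 111 ± 0.446 RPKM while HK2 fell to 0.404, and the adhesion genes EPCAM and CDH1 fell to 0.654 and 0.548. Of 21 NORAD, PUMILIO and CCR4-NOT factors, 2 rose and 7 fell (2 and 6 adjusted over the list alone). That list was not called (camera with Benjamini-Hochberg adjusted p = 0.388). The deadenylase scaffold CNOT1 fell to 0.679 and its catalytic partner CNOT6 to 0.788, while TOB1 stood higher (56.38 and 53.46 against 44.89 and 44.7 RPKM).

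Genes with a PUMILIO motif stood lower in circPRE8 sgNORAD against parental sgNORAD by a median log2 of -0.051 for at least 1 motif and -0.067 for at least 2 (camera with Benjamini-Hochberg adjusted p = 0.047 and 0.0372). Adjusted p = 0.6 with an estimated correlation for each, and genes with the reversed motif stood lower too (-0.064 and -0.093, adjusted p = 0.0372 and 0.0114). The calls were lost without parental sgNORAD replicate 1 (0.141 and 0.116) and without circPRE8 sgNORAD replicate 2 (0.0978 and 0.0911). In the whole table, 2738 genes rose and 3315 fell (6053 of 11585, 52.2%), with 97 and 118 beyond 2-fold and 165 and 184 against a log2 change of 0.5 (limma treat). Of the genes called, 45.2% rose, 35.2% with library totals, 50.9% with RLE size factors and 52.6% with upper quartile factors, so which direction held the majority depended on the scaling.

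Changes in circPRE2 and circPRE8 against the same parental sgNORAD libraries overlapped. There were 1535 genes changed the same way (890 up, 645 down), with SLC2A3, F10, SEMA3A and SAMD9 among the rises and MYC and EPCAM among the falls, and 111 changed opposite ways. Independence would give 297.1 up and 262.1 down. The 2 comparisons share their control libraries, which alone can make changes look alike. In 50 simulations with shared controls and no true change, 0.04 genes on average were called the same way in each comparison. The correlation of log2 changes was 0.501 in the simulations against 0.543 in the data. With groups of equal size and spread, a shared control fixes the simulated correlation near this value for noise of any size. The 2 correlations therefore cannot tell how much of the likeness is shared noise. The covariance, which depends on the size of the noise, was 0.0032 against 0.0369, so a part of the likeness may come from the shared controls. All groups were simulated with equal spread, while the parental sgNORAD replicates differed most, so the simulations may understate the shared noise. With 1 parental sgNORAD library as the control of each line and none shared, 1273 genes changed the same way (646 up, 627 down; independence would give 282.5 and 267.7) with replicate 1 for circPRE2, and 974 (691 up, 283 down; 215.9 and 111) with replicate 2 for circPRE2. Each of these tests takes its spread from the other groups and assumes that a lone parental sgNORAD library varies like them, while the parental sgNORAD libraries were the least alike pair (chi-square per degree of freedom 12.45, against 4.21 to 4.59 in the other groups), so calls may reflect 1 library. Opposite ways were taken by 223 and 82 genes, and the correlations were 0.391 and 0.47, over genes that are not independent replicates. Without circPRE2 sgNORAD replicate 1 the number changed the same way was 590, and without circPRE2 sgNORAD replicate 2 it was 857.

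Setting circPRE8 sgNORAD against circPRE2 sgNORAD asked how these 2 lines differed, with no library shared with the knockdown comparison in the parental line. EHF rose 9.24-fold from 2.16 ± 0.134 to 20.7 ± 0.523 RPKM (SD, n = 2; limma, Benjamini-Hochberg adjusted p = 5.56e-11). PRSS33 rose 12.6-fold (adjusted p = 1.15e-07), APOBEC3G 10.7-fold, IGFBP3 4.95-fold, SPARC 3.77-fold, the membrane scaffold gene SNTB1 3.39-fold, the growth factor gene FGF9 3.29-fold and the collagen gene COL13A1 3.15-fold. IL32 fell to 0.19, from 6.13 ± 0.186 to 1.09 ± 0.198 RPKM (adjusted p = 3.54e-08), GALNT14 to 0.206, ZNF711 to 0.216, ARRDC4 to 0.232, MAL2 to 0.234, WDR72 to 0.261, DSC3 to 0.262 and MMP14 to 0.275. MYC fell to 0.519, HK2 to 0.554 and PRKDC to 0.478, and SLC2A1 rose 1.7-fold. PUM2 did not pass (adjusted p = 0.346).

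Of 36 mitosis genes in circPRE8 against circPRE2, 29 rose and 1 fell (29 and 1 adjusted over the list alone; camera with Benjamini-Hochberg adjusted p = 1.44e-11), with KIF18A up 1.47-fold, PLK1 up 1.34-fold and CCNB2 up 1.32-fold. Of 25 integrated stress genes, 20 rose and 2 fell (21 and 2 adjusted over the list alone; adjusted p = 7.81e-09), with PSAT1 up 1.71-fold to 99.3 ± 3.33 RPKM, the glutathione-degrading CHAC1 up 2.41-fold and SESN2 up 1.49-fold. Of 44 DNA replication genes, 17 rose and 2 fell (17 and 2 adjusted over the list alone; 26 and 2 with RLE size factors; adjusted p = 8.12e-05), with the thymidylate synthase TYMS up 1.45-fold, the sliding clamp PCNA up 1.2-fold and the helicase subunit MCM5 up 1.17-fold. Of 11 replication histone genes, 9 rose and 0 fell (9 and 0 adjusted over the list alone; adjusted p = 4.75e-05), and of 14 heat shock genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.00431), with DNAJA1 up 1.56-fold and DNAJB1 up 1.28-fold. Adjusted p = 0.778 with an estimated correlation for mitosis and integrated stress, 0.543 for histones and 0.968 for DNA replication and heat shock. Not called were p53 targets (5 rises and 4 falls, 5 and 4 adjusted over the list alone; 0.587), interferon (2 and 3, 0 and 1 adjusted over the list alone; 0.892) and ribosomal proteins (0 and 8, 0 and 5 adjusted over the list alone; 0.284, and 0.0387 without circPRE2 sgNORAD replicate 1). For interferon the median and mean were below 0 (-0.031 and -0.002) and the set test pointed up. Fibroblast markers (2 and 1, 2 and 1 adjusted over the list alone; 0.318) were called without circPRE8 sgNORAD replicate 1 (0.0422), and embryonic kidney and neural markers gave 1 and 1 (1 and 1 adjusted over the list alone; 0.968). Interferon rises went to 0 without circPRE2 sgNORAD replicate 1 and up to 6 without circPRE8 sgNORAD replicate 1, and interferon falls to 1 without parental sgControl replicate 1 and up to 6 without circPRE8 sgNORAD replicate 2. For p53 targets, rises went to 3 without circPRE2 sgNORAD replicate 2 and falls to 2 without circPRE8 sgNORAD replicate 2. Rises went to as few as 8 in DNA replication, 4 in heat shock and 1 among fibroblast markers without circPRE2 sgNORAD replicate 1, which also took integrated stress falls to 1, and ribosomal falls to 1 without circPRE2 sgNORAD replicate 2.

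Genes that the NORAD guide had moved in the parental line moved the other way here. Of the 2425 that rose with the guide, 2091 (86.2%) were lower in circPRE8 than in circPRE2, 1370 of them with adjusted p under 0.05, and 74 rose again (limma, Benjamini-Hochberg), with IL32, ARRDC4, MMP14, DSC3 and MYC among the reversed. Of the 1901 that fell, 1525 (80.2%) were higher, 1024 of them called and among them CCNB2, PHGDH and PSAT1, and 98 fell again. Median log2 changes were -0.185 and 0.155, with camera adjusted p = 2.86e-24 and 1.94e-33. Adjusted p = 0.00942 with an estimated correlation for the risen genes and 0.018 for the fallen genes. By fry, which tests only whether the genes of a set move one way on balance, p was 5.41e-05 and 0.000425. The correlation of log2 changes was -0.562 over 11585 genes, and genes are not independent replicates.

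**Figure D3:**
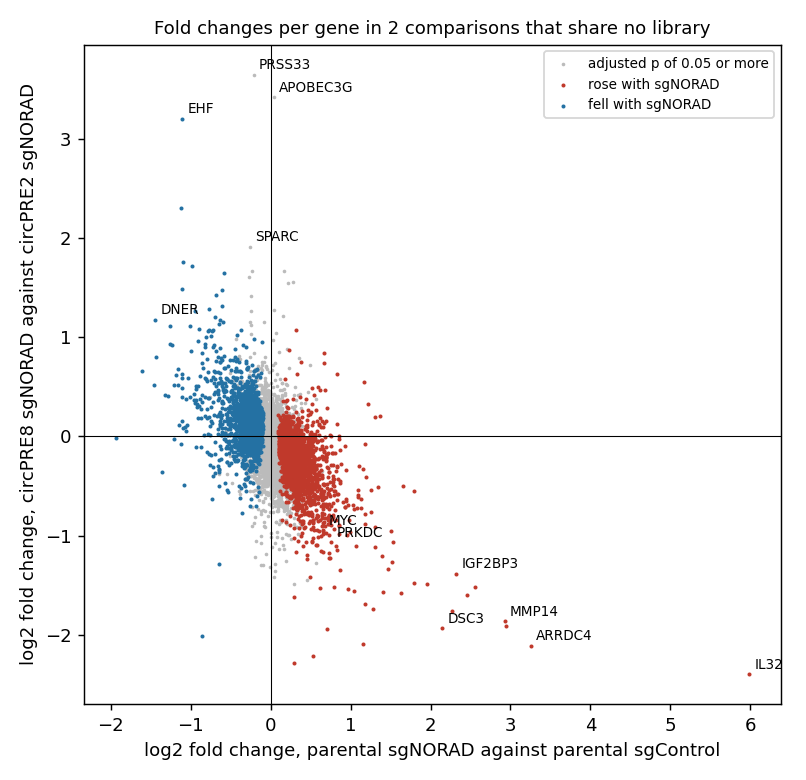
Log2 fold change per gene of parental sgNORAD against parental sgControl (horizontal) and of circPRE8 against circPRE2, each with the NORAD guide (vertical); red genes rose and blue genes fell with the guide, grey genes did not pass. Of 2425 red genes, 2091 lie below 0 on the vertical axis, with IL32, ARRDC4 and MMP14 at the lower right.

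In all, 2081 genes rose and 2975 fell in circPRE8 against circPRE2 (5056 of 11585, 43.6%), with 45 and 79 beyond 2-fold and 60 and 106 against a log2 change of 0.5 (limma treat). Of the genes called, 41.2% rose, and 54.6% rose with RLE size factors, 52.1% with upper quartile factors and 30.5% with library totals. The total was 3168 without circPRE2 sgNORAD replicate 1 (1289 up, 1879 down), and rises went to 1377 without circPRE8 sgNORAD replicate 1. The lines may differ in ways other than circPRE2 and circPRE8, which the 2 libraries per line cannot separate.

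With circPRE2 sgNORAD against parental sgControl, the question was whether the differences from the untargeted state remained in that line. IL32 was up 49.9-fold at 6.13 ± 0.186 RPKM (SD, n = 2; limma, Benjamini-Hochberg adjusted p = 2.77e-11), IGF2BP3 6.22-fold at 13.5 ± 0.336, ARRDC4 8.84-fold, MMP14 6.59-fold, RGS2 4.78-fold, KRT23 3.95-fold and the peroxidasin gene PXDN 3.81-fold. EHF was down to 0.108, 2.16 ± 0.134 against 20.8 ± 0.289 RPKM (adjusted p = 2.77e-11), SLC30A10, a manganese exporter gene, to 0.29, TXNDC5 to 0.317 and NETO2 to 0.368. Mitosis genes fell in 34 of 36 (0 and 35 adjusted over the list alone; camera with Benjamini-Hochberg adjusted p = 2.42e-18) and DNA replication genes in 37 of 44 (0 and 40 adjusted over the list alone; 1.71e-16), each with 0 rises, with the checkpoint gene MAD2L1 at 0.697 and RRM2 at 0.747. Interferon genes rose in 24 of 25 (25 and 0 adjusted over the list alone; 5.46e-11) and p53 targets in 20 of 26 (20 and 0 adjusted over the list alone; 3.98e-09), each with 0 falls, with the tethering factor BST2 up 4.73-fold, ISG15 1.81-fold, CDKN1A 1.66-fold and TP53INP1 2.26-fold. Integrated stress genes gave 1 rise and 14 falls (1 and 15 adjusted over the list alone; 3.13e-06), with the cystine transporter SLC7A11 at 0.399, and cholesterol genes 2 and 15 (2 and 15 adjusted over the list alone; 4.5e-05). Cohesin and condensin gave 1 and 13 (1 and 13 adjusted over the list alone; 4.5e-05), heat shock 1 and 11 (1 and 11 adjusted over the list alone; 0.000203) and DNA repair 6 and 17 (8 and 18 adjusted over the list alone; 0.00151). Adjusted p = 0.424 with an estimated correlation for heat shock and DNA repair and 0.366 for the other lists.

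Ribosomal proteins (14 rises, 0 falls; 14 and 0 adjusted over the list alone; camera with Benjamini-Hochberg adjusted p = 0.0406) lost that call with RLE size factors (0.223), with a replicate block (0.0607) and with 6 libraries left out in turn: parental sgControl replicate 1 (0.45), circPRE2 sgNORAD replicate 2 (0.331), and each parental sgNORAD and circPRE8 sgNORAD library (0.0645 to 0.0661). Adjusted p = 0.793 with an estimated correlation. Chromosome 20 neighbours of NORAD (9 rises and 2 falls of 14, 9 and 2 adjusted over the list alone; 0.0596) were called without parental sgControl replicate 2 (0.0402) and without circPRE2 sgNORAD replicate 1 (0.0478). Rises among ribosomal proteins went to as few as 6 without parental sgControl replicate 1, and heat shock falls to 6 and DNA repair rises to 2 without parental sgControl replicate 2. Replication histones gave 5 rises and 3 falls of 11 (5 and 3 adjusted over the list alone; 0.603), and 3 and 1 without parental sgControl replicate 1. Markers of other cells gave 2 rises and 0 falls of 3 for fibroblasts (2 and 0 adjusted over the list alone; 0.262) and 1 and 0 of 3 for embryonic kidney and neural lines (1 and 0 adjusted over the list alone; 0.483, fry 0.0136), and the 1 blood marker tested, CORO1A, rose 1.61-fold to 0.97 ± 0.00309 RPKM. PUM2 did not pass (limma, Benjamini-Hochberg adjusted p = 0.726). In total 2914 genes rose and 2062 fell (4976, 43%), and 58.6% of calls were rises, against 44.3% with RLE and 47.8% with upper quartile factors. The total was 3228 without circPRE2 sgNORAD replicate 1 (1887 up, 1341 down), and falls went to 1351 without parental sgControl replicate 2.

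For circPRE8 sgNORAD against parental sgControl the question was the same. PRSS33 was up 13.2-fold, APOBEC3G 10.3-fold, SPARC 6.38-fold, PXDN 5.59-fold at 4.68 ± 0.017 RPKM and the sulfotransferase gene SULT1A1 3.27-fold (limma, Benjamini-Hochberg adjusted p = 3.06e-09 for PXDN). S100A14, an epithelial calcium-binding protein gene (ENSG00000189334.9, chromosome 1, 153614255 to 153616986), was down to 0.247, 13.6 ± 0.111 against 55.4 ± 2.98 RPKM (SD, n = 2, limma adjusted p = 1.66e-10). The growth factor gene EREG was down to 0.282 at 45.7 ± 5.08 RPKM, the epithelial regulator GRHL2 to 0.285, CDH1 to 0.503 and MYC to 0.633. Epithelial genes did not all fall. KRT19, on the intestinal differentiation list with CDH1, stood at 605.2 and 619 RPKM against 432 and 459.7 in parental sgControl. The median log2 change of that list relative to other genes was 0.179. Of 26 p53 targets, 22 rose and 0 fell (22 and 0 adjusted over the list alone; camera with Benjamini-Hochberg adjusted p = 6.42e-12), with CDKN1A up 1.67-fold and GDF15 up 1.78-fold. Of 25 interferon genes, 22 rose and 0 fell (23 and 0 adjusted over the list alone; 9.96e-12), with BST2 up 5.43-fold and ISG15 up 1.8-fold. DNA replication genes gave 0 rises and 27 falls of 44 (0 and 29 adjusted over the list alone; 6.94e-07), with RFC5 at 0.757 and POLA1 at 0.768, and DNA repair genes 5 and 22 of 43 (6 and 23 adjusted over the list alone; 0.00303). Cholesterol genes gave 2 and 15 (2 and 16 adjusted over the list alone; 0.000175), cohesin and condensin 1 and 12 (1 and 12 adjusted over the list alone; 0.000645), replication histones 6 and 0 (7 and 0 adjusted over the list alone; 0.000645) and epithelial-mesenchymal genes 7 and 1 (7 and 1 adjusted over the list alone; 0.00253), with VIM up 2.48-fold and ZEB1 up 1.87-fold. Adjusted p = 0.259 with an estimated correlation for p53 targets and epithelial-mesenchymal genes, 0.31 for histones, 0.421 for interferon and 0.427 for the rest.

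Mitosis genes in that comparison gave 1 rise and 14 falls of 36 (1 and 14 adjusted over the list alone; camera with Benjamini-Hochberg adjusted p = 0.0151; adjusted p = 0.942 with an estimated correlation), with BUB1 at 0.794 and KIF18A up 1.28-fold, and the call was lost without circPRE8 sgNORAD replicate 2 (0.0824). Falls went to as few as 6 in mitosis and 15 in DNA replication without that library, and to 7 in cohesin and condensin and 13 in DNA repair without parental sgControl replicate 1. DNA repair rises went from 5 to 1 without circPRE8 sgNORAD replicate 1, and cholesterol rises from 2 to 1 without parental sgControl replicate 2. Fibroblast markers rose in 3 of 3 (3 and 0 adjusted over the list alone; 0.0172; adjusted p = 0.427 with an estimated correlation), with SPARC the strongest, and in 1 without parental sgControl replicate 2. Embryonic kidney and neural markers gave 1 and 1 of 3 (1 and 1 adjusted over the list alone; 0.659), and CORO1A rose 1.35-fold. Leaving out parental sgControl replicate 2 also made ribosomal proteins a call (0.0358, against 0.61). Chromosome 20 neighbours (6 and 2, 7 and 3 adjusted over the list alone; 0.0823) became a call without parental sgControl replicate 1 (0.0372). Genes with at least 1 and at least 2 PUMILIO motifs were lower by a median log2 of -0.061 and -0.074 (0.00679 and 0.00518; adjusted p = 0.499 with an estimated correlation), and genes with the reversed motif by -0.065 and -0.075. PUM2 did not pass (0.585). In total 2322 genes rose and 2370 fell (4692, 40.5%), with 75 and 46 beyond 2-fold, and 49.5% of calls were rises, against 40.5% with library totals (1805 up, 2647 down). The total was 2967 without circPRE8 sgNORAD replicate 2 (1409 down), and falls went to 1568 without parental sgControl replicate 1.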

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

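Of 354 counts under other settings, 313 stayed within 1.5 times the main count and 41 moved. Of 24 values for the direction in circPRE8 against circPRE2 of genes changed by the NORAD guide, 24 stayed the same. Relative to other genes the median ran from -0.192 to -0.184 for risen genes and from 0.21 to 0.23 for fallen genes. Plain medians with fry were -0.185 and 0.155. With all libraries kept, adjusted p (camera or fry, Benjamini-Hochberg) was at most 0.018. The risen and fallen genes were always those of the main fit and were not chosen anew without a library. Leaving out a parental library could therefore hardly move these values, which say little about the choice of genes. Of 1584 fixed-list values, 1416 stayed the same, 87 lost a call, 30 gained one and 51 changed sign, none of the last a call before or after. Of 180 motif-list values, 144 stayed the same, 13 lost a call, 12 gained one and 11 changed sign. Of 8481 values for named genes, 7982 stayed the same, 488 lost and 2 gained a call, and 9, all of PUM2, changed sign. List values below are median log2 changes relative to other genes, except for fry, where they are plain medians. With camera or fry, a change of sign in a list is one in the direction of the test. That direction can differ from the sign of the median. The cause of these shifts was not tested.

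Against a log2 change of 0.5 (limma treat), changed, risen and fallen genes were 99, 54 and 45 in parental sgNORAD against parental sgControl, 23, 19 and 4 in circPRE2 and 349, 165 and 184 in circPRE8 against parental sgNORAD, and 166, 60 and 106 in circPRE8 against circPRE2. Against parental sgControl they were 168, 119 and 49 in circPRE2 and 159, 86 and 73 in circPRE8. With no filter, falls in circPRE2 against parental sgNORAD were 536 and not 916.

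With fry the sign of the test changed, at these medians, for DNA replication in circPRE8 against parental sgNORAD (0.013), and in circPRE8 against circPRE2 for PUMILIO targets (0.062), CCR4-NOT factors (0.018), DNA repair (-0.019), interferon (-0.031), cholesterol (0.014), hypoxia (-0.005) and mitochondrially encoded genes (-0.02). In circPRE8 against parental sgControl it changed for PUMILIO targets (0.019), Wnt genes (-0.001) and intestinal differentiation (0.177). With RLE size factors it changed for p53 targets in circPRE8 against parental sgNORAD (0.003) and, in circPRE8 against circPRE2, for chromosome 20 neighbours (0.048) and mitochondrially encoded genes (0.018). With a replicate block it changed for embryonic kidney and neural markers in circPRE8 against circPRE2 (0.037) and oxidative phosphorylation in circPRE8 against parental sgControl (0.012).

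For at least 1 PUMILIO motif, fry turned the test from down to up in parental sgNORAD against parental sgControl (median 0.022). The same held for circPRE2 against parental sgNORAD (-0.005, a median still below 0) and against parental sgControl (0.018). With fry a call was gained in circPRE8 against circPRE2 (-0.061) and lost in circPRE8 against parental sgControl (-0.047). For at least 2 motifs, fry turned the test from down to up in circPRE2 against parental sgNORAD (median -0.011, still below 0) and parental sgControl (0.016). It gained a call in circPRE8 against circPRE2 (-0.087) and lost one in circPRE8 against parental sgControl (-0.069). Random lists matched on 3' UTR length left differences, for at least 1 and at least 2 motifs, of -0.007 and -0.01 (gained) in circPRE2 against parental sgNORAD, -0.015 and -0.02 (gained) in circPRE2 against parental sgControl, and -0.007 and -0.008 (lost) in circPRE8 against parental sgNORAD. Matched on GC content too, the circPRE2 medians lay at percentiles 80 and 74.2 against parental sgNORAD. Against parental sgControl they lay at 31.4 and 47.9, so no shift stood out in either comparison. On length alone, lists with the reversed motif lay at percentile 0 in both circPRE2 comparisons. For at least 2 motifs in parental sgNORAD against parental sgControl, lists matched on length left -0.003, against 0.01 without matching (sign changed). With principal transcripts the direction of the set test changed there, while the difference stayed above 0, at 0.008. An estimated correlation lost the calls at -0.051 and -0.067 in circPRE8 against parental sgNORAD and at -0.061 and -0.074 in circPRE8 against parental sgControl, and principal transcripts lost 1 at -0.049. In circPRE8 against circPRE2 at least 2 motifs became a call with a motif of any base at its variable place (-0.052), with RLE (-0.053) and with a replicate block (-0.054). PUM2 changed sign with library totals in parental sgNORAD against parental sgControl (0.005) and with voom in circPRE2 against parental sgNORAD (0.003).

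With each library left out in turn, the lone library left in its group is assumed to vary like the other groups. In circPRE2 against parental sgNORAD 713 to 2359 genes changed (475 to 1245 up, 238 to 1114 down), in circPRE8 against circPRE2 3168 to 5484 (1289 to 2241 up, 1879 to 3243 down), in circPRE2 against parental sgControl 3228 to 5406 (1887 to 3176 up, 1341 to 2230 down) and in circPRE8 against parental sgControl 2967 to 5158 (1409 to 2602 down). The overlap of circPRE2 and circPRE8 changes ran from 590 to 1643, and with a separate parental sgNORAD library as control for each line it was 974 or 1273. PUM2 ran from -0.083 to 0.063 in parental sgNORAD against parental sgControl, -0.088 to 0.058 in circPRE2 and -0.025 to 0.121 in circPRE8 against parental sgNORAD, and -0.067 to 0.018 in circPRE2 against parental sgControl.

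List medians ran as follows over the same omissions. In parental sgNORAD against parental sgControl: mitochondrially encoded -0.775 to 0.274, histones 0.027 to 0.119, fibroblast -0.102 to 0.128, at least 1 motif -0.018 to 0.011, at least 2 motifs -0.012 to 0.027. In circPRE2 against parental sgNORAD: PUMILIO targets -0.049 to 0.033, intestinal differentiation 0.009 to 0.04, mitochondrially encoded -0.078 to 1.068, histones 0.031 to 0.17. In circPRE8 against parental sgNORAD: cohesin and condensin -0.079 to -0.003, DNA replication -0.004 to 0.057, p53 targets -0.015 to 0.021, mitochondrially encoded -0.073 to 0.986, at least 1 motif -0.063 to -0.037, at least 2 motifs -0.083 to -0.047. In circPRE8 against circPRE2: chromosome 20 neighbours 0.002 to 0.052, interferon -0.073 to 0.128, cholesterol 0.031 to 0.066, mitochondrially encoded -0.129 to 0.159, embryonic kidney and neural -0.049 to 0.12, at least 1 motif -0.045 to -0.026, at least 2 motifs -0.062 to -0.043. In circPRE2 against parental sgControl: oxidative phosphorylation -0.021 to 0.032. In circPRE8 against parental sgControl: PUMILIO targets -0.019 to 0.029, heat shock -0.043 to 0.015, Wnt genes -0.027 to 0.028, ribosomal proteins -0.022 to 0.062, oxidative phosphorylation -0.012 to 0.029.

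With replicate numbers as a block, 4421, 2229, 6121, 5133, 5056 and 4777 genes changed in the 6 comparisons in the order of the results text. Deviations of equally numbered replicates correlated at -0.17 to 0.21 between groups, over genes that are not independent replicates. Whether equal numbers mark pairs stayed open, since the labels do not say and these values cannot exclude a shared day. The count-based tests of edgeR and DESeq2 were not run, because the values are RPKM.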

Other observations

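APOBEC3G was picked out after the levels had been seen. It was the only gene at 1 RPKM or more in both libraries of a group and at 0.2 RPKM or less in all others: 1.1 and 1.64 RPKM in circPRE8 sgNORAD (264 and 434 reads) against 0.0322 to 0.057 RPKM elsewhere (5 to 14 reads). No gene was switched off by the same limits. A test would be to measure APOBEC3G by PCR in further circPRE8 clones and in the line before any guide was added.

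Genes moved by the NORAD guide moved back in circPRE8 against circPRE2, in libraries not shared with the knockdown comparison; of the tests here, only that on NORAD itself was chosen after the result was seen. The correlation of log2 changes over genes (which are not independent replicates) was -0.562, and it was -0.557 once trends with gene length, 3' UTR length, GC content and expression were removed and -0.55 without the shallow parental sgNORAD replicate 1, so neither of these causes accounts for it. Whether NORAD was still expressed in circPRE8 sgNORAD stayed open, since 0 entries for NORAD were analysed here. A hypothesis is that circPRE8 offsets part of the loss of NORAD, for IL32 and mitosis genes but not for p53 target or interferon genes. Nor would this hold for MYC, which fell to 0.633 of the level in parental sgControl. The DNA replication, cohesin and condensin, and cholesterol lists still fell against parental sgControl. None of these lists was called in circPRE8 against parental sgNORAD (camera at the preset correlation). Their medians there, relative to other genes, were 0.034, -0.046 and 0.125. Other hypotheses are that the circPRE8 cells kept more NORAD or were a separate clone. Any of these hypotheses could give -0.557. Measuring NORAD in all 4 groups, and repeating with independent pools and a circPRE8 line carrying the control guide, would separate these.

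Chromosome 21 was singled out after all chromosomes had been looked at, the test of its proximal against its distal part was chosen after the result was seen, bootstrap intervals were added after the first values, and the rule for judging them was then made stricter. Other chromosomes were called too: chromosome 19 was higher against parental sgControl in circPRE8 (camera over chromosomes, Benjamini-Hochberg adjusted p = 0.00188) and in circPRE2 (0.0465), and chromosome 18 lower in circPRE2 against parental sgNORAD (0.0451), none of them with an estimated correlation (adjusted p = 0.617, 0.993 and 0.988 with an estimated correlation). The 101 tested genes of chromosome 21 were higher than other genes by a median log2 of 0.107 (bootstrap 95% interval 0.064 to 0.14) with the NORAD guide in the parental line, with 37 rises and 7 falls, and lower by -0.095 (-0.138 to -0.039) in circPRE8 against circPRE2, with 10 rises and 45 falls (camera over chromosomes, Benjamini-Hochberg adjusted p = 0.00914 and 0.0995; adjusted p = 0.999 with an estimated correlation for the guide). With trends in length, GC content and expression removed the first value was 0.101 (0.059 to 0.13), and 71.3% of the genes (Wilson interval 61.8 to 79.2) lay above the median of the others. For the guide in the parental line, these values argue against such a trend or a few strong genes as the whole account. For circPRE8 against circPRE2 the values were -0.077 (-0.133 to -0.025) and 66.3% on the side of the shift (56.7 to 74.8). There a trend and a few strong genes both stayed open. The stricter rule had to be met in both comparisons, so by it both stayed open for the pattern of chromosome 21 as a whole. Against parental sgNORAD, the median of these genes relative to others was -0.119 (-0.17 to -0.057) in circPRE8 and -0.019 (-0.053 to 0.004) in circPRE2. Against parental sgControl it was -0.032 (-0.073 to 0.033) in circPRE8 and 0.072 (0.045 to 0.112) in circPRE2. With the guide in the parental line, the proximal and distal parts differed by -0.005 (-0.092 to 0.064). A change in copies of the whole chromosome in part of the cells could give this. Other shifts not tied to position could too, and the interval is wide beside the shift of 0.107. Counting chromosome 21 by in situ hybridisation in the 4 groups would test a change in copies, since no copy number was measured.

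Genes with a PUMILIO motif stood lower in circPRE8 against parental sgNORAD; the test on length and base composition was chosen after the result was seen, that on the motif itself before. The list median lay at percentile 51.4 of random lists matched on 3' UTR length and GC content, so those features may account for the shift there. In that comparison, genes with the motif alone (1859) differed from genes with the reversed motif alone (1241) by 0.016 (-0.011 to 0.037). Recognition of the motif would need a value below 0. The difference lay above 0, but its interval reached below 0, so a small effect of the motif was not excluded. Against parental sgControl, the shifts in circPRE8 were larger (-0.061 for at least 1 motif, -0.074 for at least 2). The medians lay at percentiles 2.5 and 9.1 of lists matched on length and GC content, and at 0 on length alone. Genes with the reversed motif stood as low there (-0.065 and -0.075). Their medians lay at percentiles 17.9 and 58.5 on length and GC content, and at 0 and 1.5 on length alone. Part of these genes carry both motifs, and genes with 1 motif alone were not compared there. Recognition of the motif therefore stayed open in that comparison too. Reporter genes with intact and mutated motifs in each line would test PUMILIO activity directly.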
